A study of Mus musculus with 8 samples.

How the data were processed

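Single-cell RNA-seq libraries had been made from the hypothalamus of wild-type C57BL/6J mice at 6 labelled ages. Per the labels, polyA RNA of single cells was captured with a droplet method, a small volume of lymphocytes was added as spike-ins, and the P10 and P23 mice were perfused before dissection. The series' design text gives E15.5 and E17.5 for the embryonic ages, which the sample labels give as E15 and E17, and numbers of 8, 7, 4, 4, 3 and 3 for the 6 ages without saying what they count. The 8 libraries belong to 3 library batches per the labels: batch 2 holds 6 libraries, 1 per age, batch 3 holds P2 replicate 2 and batch 1 holds P10 replicate 1.

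The deposited table holds, per the file headers, a score for each cell and each of 395 activating regulons. A regulon is a transcription factor with its inferred target genes, and the score is a rank-based area under a recovery curve within the cell. The values run from 0 to 0.937, none are missing, and 21.9% are 0. The tool that made the scores, the targets of each regulon and the filter on cells are not given in the sources used here. The submitters' processing notes name Cell Ranger 2.2.0, Seurat 3.0 and the genome builds mm10 and GRCm38, with no role or order. A regulon is a set of genes and the table has no coordinates, so no genomic positions are given, and a genome of another build was not used. Since each score is relative to the other genes of its cell, a cell with fewer detected genes can have lower scores for many regulons together. Counts of molecules were not analysed here, so depth per cell is unknown, no thinning to a common depth could be made, and doublets were not treated. As stand-ins, the median number of regulons above 0 per cell was between 293 (P10 replicate 1) and 315 (P2 replicate 2), and the mean score over regulons between 0.036 (P10 replicate 1) and 0.0498 (E15). P10 replicate 1 had the lowest value of both and stood apart in the mean score, where P23 was next lowest at 0.0421. Because the score is rank-based, differences and SDs are given and no fold changes.

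Cells were assigned to libraries by the prefix of their names. For P2 and P10, 1 of the 2 prefixes carries a batch number that matches the labels and the other carries none, so the prefix without a number was taken as the batch 2 library by elimination. The ages do not rest on this, only the batches do. All 33893 cells were assigned, and 0 were left out. Libraries of 1 age were not copies of each other: 0 cells had identical scores. The cell is not a replicate: the mean score of each regulon was taken per library, which leaves 8 values per regulon. The SD given with a phase is between its libraries.

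Means were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend), with Benjamini-Hochberg adjustment over the 395 regulons and a threshold of 0.05. The designs, lists of factors, cell type markers and the rule for naming regulons were written before the data were examined. The main trend is the slope on age step, the ages numbered from 1 to 6, over all 8 libraries. The phases were compared in 1 fit of all 8 libraries. The same trend was fitted to means over neuron-like cells, whose makeup by cluster differed between libraries, and to the neuron-like minus glia-like difference within each library, where both classes had to have 20 cells in every library; that last fit used no mean-variance trend, a choice that had been left open before the data were examined. Lists were tested with fry, and with camera at an estimated correlation and at a preset one of 0.01, over the 9 lists with 5 or more members. Named regulons are, for each of the 4 trend or phase results, the 12 with the largest standardized increase and decrease (slope or difference divided by the SD of the score between cells within libraries) among those that passed. Where fewer than 5 passed, the 3 with the smallest p in that direction are named. Members of the fixed lists could be named as well. A few regulons that the rule or the lists would name are not reported here, while counts include them. Factors are matched by symbol, and many fixed factors had no regulon in the table.

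For the classes, scores were standardized within each library, limited to 5 SDs, reduced to 20 principal components and clustered with Leiden (leidenalg 0.10.2, igraph 0.11.9, resolution 1) on a graph of 15 nearest neighbours (scikit-learn 1.9.0), in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Several of these choices were made after the data had been seen. A first clustering of the scores as deposited followed the libraries: of 18 clusters, 7 held over 75% of their cells from 1 library, against 0 of 17 after standardizing within libraries. Standardizing within libraries assumes that they hold comparable mixes of cells, and limits what a share can show, since the regulons that define a class can themselves change with age. A cluster was named when 3 or more of its 10 regulons with the largest standardized difference from other cells were fixed markers of 1 class, and more than of any other class. This naming rule too was set after the data had been seen. No cluster was led by oligodendrocyte, microglial, lymphocyte, vascular or erythroid regulons. Shares were tested against age step with exact permutation tests over all 40320 orders of the libraries, two-sided, with exact Clopper-Pearson 95% intervals per library.

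The limma fits were tested on simulated data drawn from the real means and spreads of the 395 regulons, with 80 regulons changed in each of 20 runs. Noise was drawn independently for each regulon. Real regulons of a list moved together, with correlations estimated by camera from 0.224 to 0.598, so the simulated false calls may not describe the real fits. For the age trend, a slope of 1 residual SD per age step was recovered for 81.5% of the changed regulons and a slope of 0.5 for 18.5%, with a mean of 2.5 false calls; 1 of 20 runs without change gave any call. For the change from embryonic to neonatal libraries, a difference of 4 residual SDs was recovered for 36% and one of 2 for 4.2%. For the change from neonatal to later postnatal libraries these values were 67.8% and 10.8%. The phase comparisons could therefore detect only large differences.

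The alternatives chosen before the data were examined were centring each cell on its mean over regulons, the rank of a regulon within its cell, the share of cells above the 90th percentile, log2(mean score + 0.001), eBayes without trend, robust eBayes, a filter for regulons above 0 in 20% of the cells of a library, leaving out the 10% of cells with fewest regulons above 0, log2 of days since conception with birth at day 19, library batch as a term, each library left out, and clustering resolutions of 0.5 and 2. Batches 1 and 3 hold 1 library each, so a batch term takes up these libraries and the fit is close to that of batch 2 alone; the 2 are not separate checks. Added after the data had been seen were the cells outside glia-like clusters, batch 2 alone for the regulon counts and lists, the lists in neuron-like cells, a mean-variance trend in the fit of the neuron-like minus glia-like difference, and leaving out the 2 libraries farthest from the median age. Figures were drawn with matplotlib 3.10.9.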

Results

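The data follow the developing mouse hypothalamus, the brain region that governs hormone release, feeding, sleep and body temperature, in wild-type C57BL/6J animals. The table analysed held 33893 cells from 8 droplet-based single-cell RNA-seq libraries at 6 labelled ages. E15 and E17 (embryonic days) had 1 library each, P0 (the day of birth) 1, P2 2, P10 2 and P23 1. The libraries held between 421 cells, at P23, and 10376 cells, at E17. For each cell the table gave 395 scores, each for 1 regulon, meaning a transcription factor together with the genes inferred to be activated by it. A score runs from 0 to 1 and is higher when the regulon's genes rank high among the genes of that cell, so it measures the targets and not the transcript of the factor itself. No molecule counts were used here, so the sequencing depth behind a score is unknown. The libraries are named by age and replicate number, and were compared as a trend over the 6 ages in order and between the embryonic (n = 2), neonatal (P0 and P2, n = 3) and later postnatal (P10 and P23, n = 3) phases. The labels do not say that the libraries came from separate animals or pools. The limma p-values set a change against the spread of these libraries around the fitted trend or phase means, part of which may be technical. With 1 library at 4 of the ages, that spread mixes differences between libraries with differences between ages. The same holds for the SD of a phase, which for the embryonic phase is between E15 and E17.

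The first comparison asked which regulons changed with age over all cells. Per the labels the P10 and P23 mice were perfused, so here and in the later age trends the late ages cannot tell age from perfusion. Hdac2, Sox4 and Sox11 had the largest decreases relative to the spread between cells, and Tef, Nfe2l1 and Pura the largest increases. Sox4 and Sox11, factors of differentiating neurons, fell from mean scores of 0.0948 ± 0.0209 and 0.0927 ± 0.0192 (SD, n = 2) in the embryonic libraries to 0.0366 ± 0.000924 and 0.0448 ± 0.00377 (SD, n = 3) in the later postnatal ones. The regulon of the related factor Sox12 fell from 0.171 ± 0.00172 to 0.0708 ± 0.00978. Hdac2, a histone deacetylase, fell from 0.0928 ± 0.00871 to 0.0351 ± 0.0136, and Ezh2, the catalytic subunit of a Polycomb complex, fell from 0.0608 ± 0.0182 to 0.0199 ± 0.0033. Smarca4, the motor of a chromatin remodelling complex, Kdm5b, a histone demethylase, Tcf12, Yy1, Maz, Srebf2 and Creb1 completed the 12 regulons with the largest standardized decrease. Tcf12 differed greatly between the embryonic libraries, at 0.101 ± 0.0942. The regulon with the largest rise in score was Pura, a protein that binds single-stranded nucleic acids, which went from 0.0379 ± 0.0179 in the embryonic libraries through 0.0799 ± 0.0109 in the neonatal ones to 0.255 ± 0.0206 in the later postnatal ones. Nr3c2, the mineralocorticoid receptor, rose from 0.0504 ± 0.0046 to 0.155 ± 0.0423. Tef and Hlf, clock-controlled factors of 1 family, rose from 0.0441 ± 0.00281 to 0.0705 ± 0.0114 and from 0.0298 ± 0.000351 to 0.0595 ± 0.0175. Nfe2l1, Zeb1, Foxo1, Klf16, Tfe3, Creb3l1 and Nfyc were also among the 12 regulons with the largest standardized increase.

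In the limma fit of the slope per age step, 25 regulons rose and 70 fell at an adjusted p below 0.05. Sox4 fell by 0.0151 per age step (SE 0.00184, adjusted p = 0.00198) and Pura rose by 0.0535 (SE 0.00964, adjusted p = 0.00465), while Hlf lay at the threshold (adjusted p = 0.0499). Of the calls, 26.3% were rises. With each cell centred on its mean over all regulons, 60 regulons rose and 52 fell, so that 53.6% of the calls were rises, and all 24 regulons chosen by the naming rule kept their direction and their call. By the share of cells above the 90th percentile, 17 of the 24 lost their call, among them Pura (adjusted p = 0.0525), Nr3c2 (0.0544), Sox4 (0.0548), Ezh2 (0.0587), Sox11 (0.0609), Tcf12 (0.0834) and Tef (0.0878), while Hdac2, Sox12, Smarca4, Maz, Srebf2, Creb1 and Nfyc kept theirs. Of the 24, 13 lost their call without E15, 14 without P23, 7 without E17 and 7 without P0. The rank of a regulon within its cell gave 62 rises, the share of cells above the 90th percentile 5, library batch as a term 43 and the 6 libraries of batch 2 alone 40. Of the 70 falls, 62 were also called with library batch as a term and 59 in batch 2 alone, and Kdm5b lost its call in both (adjusted p = 0.0674 and 0.0702). The counts varied with the libraries used: without E15 they were 6 and 30, and the rises numbered 10 without E17, 12 without P0, 6 without P23 and 43 without P10 replicate 1. Fewer samples alone can end calls, and the slopes of lost calls did not all shrink. Without E15 the slope of Tef was 0.00811 against 0.00705 over all libraries, that of Hlf 0.00952 against 0.00758, and that of Zeb1 0.00908 against 0.00967.

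**Figure D1:**
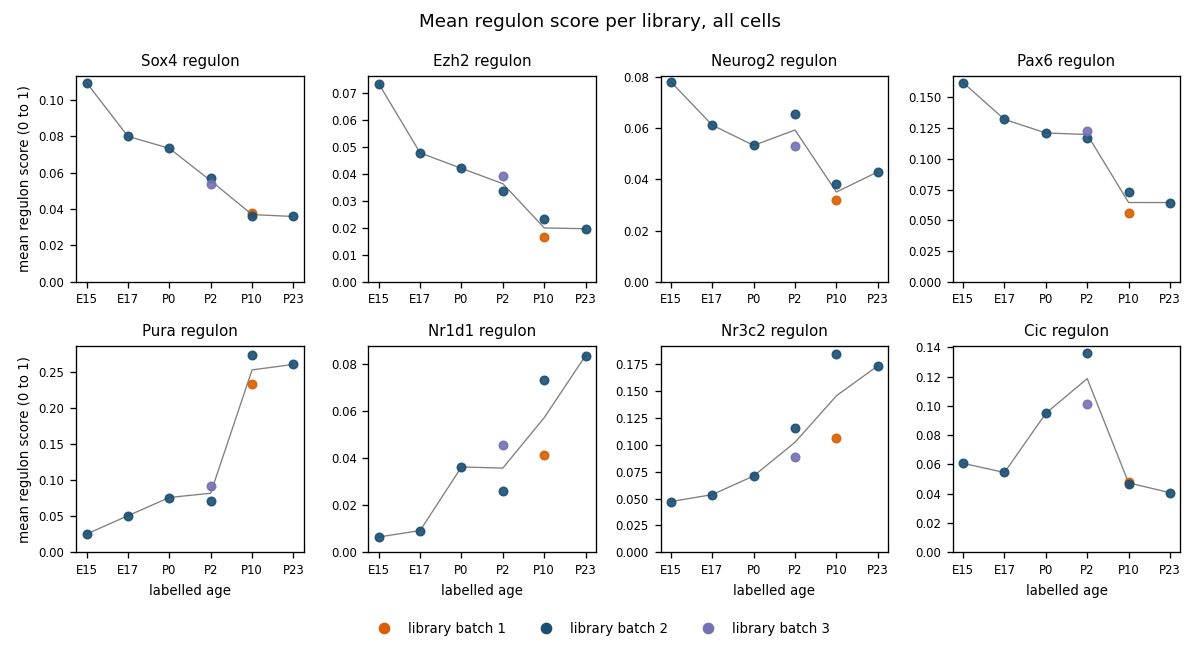
Mean regulon score per library (vertical axis, 0 to 1) against labelled age (horizontal axis) for 8 regulons named in the text, over all cells. Each point is 1 library, coloured by library batch, and the grey line joins the means of the ages. Sox4 goes from 0.11 at E15 to 0.0359 at P23, Pura from 0.0253 to 0.26, and Nr1d1 from a mean of 0.00785 in the embryonic libraries to 0.0659 in the later postnatal ones.

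Lists of factors fixed before the data were examined were tested with limma's fry, which asks whether a list's regulons move one way on balance, over the 9 lists with 5 or more members present. As background for the counts in each list, 70 of all 395 regulons fell and 25 rose, and 63.8% of all slopes were below 0. The immature neuron and neurogenic list fell (adjusted p = 0.00719; adjusted p = 0.809 in camera with an estimated correlation): of its 7 regulons, 4 fell, namely Sox4, Sox11, Neurog2 and Neurod1, and none rose, while 5 fell adjusted over the list alone. Neurog2, which starts neuronal differentiation, went from 0.0696 ± 0.0119 in the embryonic to 0.0377 ± 0.00549 in the later postnatal libraries, and Neurod1 from 0.0994 ± 0.0177 to 0.0528 ± 0.0108. The cell cycle and progenitor list fell too (adjusted p = 0.0213; adjusted p = 0.809 in camera with an estimated correlation). Of its 14 regulons, 4 fell over all regulons and 5 adjusted over the list alone. The 4 were E2f1 (0.0379 ± 0.00841 to 0.0165 ± 0.00161) and E2f2 (0.0289 ± 0.0028 to 0.00849 ± 0.00367), which drive genes of DNA replication, Ezh2 and the DNA repair factor Brca1. At a clustering resolution of 2, a cluster of 807 cells was named cycling-like, with E2f1 and Ezh2 at its top. It held 4.72% of cells at E15, 2.37% at E17, 1.94% at P0, 0.27% and 1.43% at P2, 0.63% and 0.41% at P10, and 0.24% at P23. Whether this share bears on the fall of the list was not tested. The activity, circadian and hormone response list rose (adjusted p = 0.0213; adjusted p = 0.667 in camera with an estimated correlation). Of its 16 regulons, 6 rose and 1 fell over all regulons, and 9 rose and 1 fell adjusted over the list alone. Among the 6 were Tef, Hlf, Nr3c2, the clock repressor Nr1d1 (0.00785 ± 0.00193 to 0.0659 ± 0.0221) and the thyroid hormone receptor Thrb (0.0222 ± 0.00117 to 0.0442 ± 0.0115). The 1 that fell was Creb1, a factor activated by cyclic AMP. Beside this list, all 3 regulons of the immediate early and dissociation response list had slopes above 0 (median standardized slope 0.354), and 2 rose adjusted over the list alone. Per the labels, the P10 and P23 mice were perfused. Camera, which sets a list against the other regulons, thus called none of these 3 lists with an estimated correlation, and all 3 with the preset one (adjusted p = 0.0424, 0.0424 and 1.49e-05). The cell cycle list lost its call without E15 (adjusted p = 0.145), P0 (0.0535), P10 replicate 2 (0.0519) or P23 (0.0924), and the activity list lost it without E15 (adjusted p = 0.099), E17 (0.0644), P0 (0.0535) or P23 (0.116).

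The neuron list of 26 regulons did not pass as a whole (fry adjusted p = 0.0639; 0.0439 with each cell centred; adjusted p = 0.809 in camera with an estimated correlation), although 9 of its members fell, and 9 adjusted over the list alone. Among them were Lhx1, Lhx5, Dlx5 and Bcl11a. Of 21 regulons of hypothalamic and neuroendocrine identity, 5 fell, among them Lhx1, Hmx3, Dlx5 and Lmx1a, with 5 adjusted over the list alone, and the list did not pass (adjusted p = 0.128). Emx2 and Pax6 fell among 14 regulons of astrocytes, ependymal cells and tanycytes (adjusted p of the list 0.327; 2 adjusted over the list alone), no larger a share than over all regulons. Among 8 microglial regulons 3 fell, including Spi1, the main factor of the microglial lineage, and Maf, with 3 adjusted over the list alone (adjusted p of the list 0.0956; 0.0391 without P2 replicate 2). Spi1 went from 0.0253 ± 0.0049 to 0.00402 ± 0.00288. No cluster of cells was led by microglial regulons, and the P10 and P23 mice were perfused. Yy1 and Max fell among 9 regulons of broad transcription (adjusted p of the list 0.275; 2 adjusted over the list alone). Lymphocytes had been added to the libraries as spike-ins, and none of the 5 lymphocyte regulons changed, nor did any adjusted over the list alone (adjusted p of the list 0.399). The lists with under 5 members were not tested as sets. Foxd1 fell among 3 vascular regulons, with 1 adjusted over the list alone. None of 4 oligodendrocyte regulons, 2 erythroid regulons or 3 immediate early and dissociation response regulons passed, and adjusted over the list alone this was so for the first 2 lists, while 2 of the last list passed as rises.

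**Figure D2:**
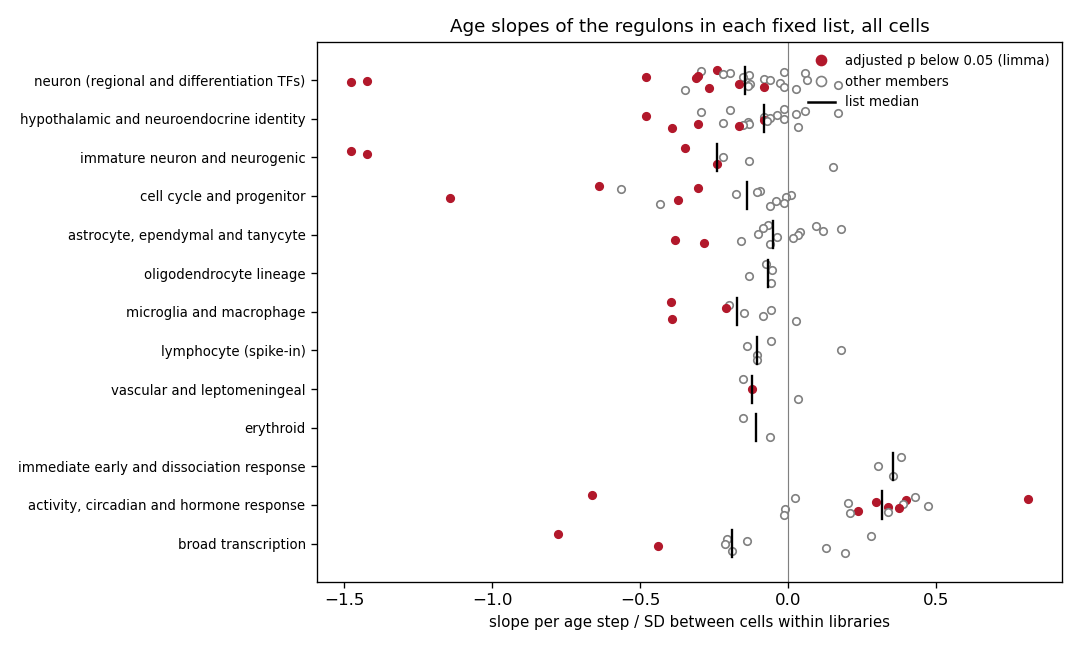
Slope of each list member's mean score per age step, divided by the SD of the score between cells within libraries (horizontal axis, no unit), for the 13 fixed lists (vertical axis). Filled points passed an adjusted p of 0.05 in limma over all 395 regulons, open points did not, and black bars are list medians. The medians of the immature neuron list (-0.241) and the activity, circadian and hormone list (0.317) lie on opposite sides of 0.

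The next comparison was between the embryonic and the neonatal libraries, which spans birth. At an adjusted p below 0.05 in limma, 1 regulon rose and 1 fell. Ahrr, the repressor of the aryl hydrocarbon receptor, fell from 0.038 ± 0.00163 (SD, n = 2) to 0.0162 ± 0.0023 (SD, n = 3; limma adjusted p = 0.0289). No other regulon passed, while 42 had an unadjusted p under 0.05. The regulons next in line did not pass: Nfe2 stood at 0.016 ± 0.00292 and 0.0327 ± 0.00276, Cic at 0.0577 ± 0.00441 and 0.111 ± 0.022 (both adjusted p = 0.0772), Foxd1 at 0.0143 ± 0.00338 and 0.00596 ± 0.00118, and Mycn had an adjusted p of 0.0701, the same as Foxd1. Limma called 0 regulons with each cell centred, by the share of cells above the 90th percentile, without a mean-variance trend, with library batch as a term and in batch 2 alone (46, 54, 34, 33 and 32 at an unadjusted p under 0.05), as well as without E15, P0 or P10 replicate 2 (18, 40 and 48). By rank within the cell there were 5 rises and 6 falls, on the log2 scale 3 and 0, and outside glia-like clusters 2 and 4. There were 0 rises and 8 falls without E17, 3 and 0 without P2 replicate 1, 1 and 0 without P2 replicate 2, and 0 and 1 without P10 replicate 1.

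From the neonatal to the later postnatal libraries, 3 regulons rose and 18 fell in limma at an adjusted p below 0.05. Per the labels, the mice of the later postnatal libraries (P10 and P23) were perfused, so this comparison cannot tell age from perfusion. Pura rose by 0.175 (SE 0.015, adjusted p = 0.000324). Nfyc, a subunit of the CCAAT-binding factor NF-Y, rose from 0.037 ± 0.00461 to 0.0785 ± 0.00161 (SD, n = 3 in each phase), and Prrx2, a homeobox factor, from 0.0101 ± 0.00945 to 0.0361 ± 0.00827. The largest standardized decrease was that of Cic, a transcriptional repressor, from 0.111 ± 0.022 to 0.0452 ± 0.00395 (adjusted p = 0.00996). Spi1, Runx1 and Nfe2 fell from 0.0196 ± 0.00399, 0.0367 ± 0.00588 and 0.0327 ± 0.00276 to 0.00402 ± 0.00288, 0.0115 ± 0.00304 and 0.00995 ± 0.00415. Pax6, a factor of neural progenitors and some neurons, fell from 0.12 ± 0.00301 to 0.0645 ± 0.00868. Max, Klf10, E2f2, Emx1, Zfp454 and Zfp319 fell as well. Library batch as a term left 4 rises and 2 falls, with Pura, Nfyc, Prrx2 and Zfp454 among those kept, and batch 2 alone also gave 4 and 2. The calls of Cic, Spi1, Nfe2 and Runx1 (each adjusted p = 0.057), Max, Zfp319, Pax6, Emx1, E2f2 and Klf10 were lost with that term. There were 43 falls on the log2 scale, 29 outside glia-like clusters, 10 without a mean-variance trend and 0 by the share of cells above the 90th percentile (66 regulons at an unadjusted p under 0.05 in limma), and 20 rises by rank. Centring each cell left 3 rises and 4 falls, so that rises went from 14.3% to 42.9% of the calls, and ended the calls of Runx1 (adjusted p = 0.0529), Spi1 (0.243), Max, Klf10, E2f2, Emx1 and Zfp454. The falls numbered 2 without P23, and 8 without P2 replicate 2, and the rises 10 without P10 replicate 1 and 6 without P10 replicate 2.

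Cells were then grouped by their scores into 17 clusters. Clusters 1, 4, 6 and 10 were called neuron-like from regulons such as Dlx1, Meis2, Isl1, Lhx1, Lhx5 and Sox11, and clusters 5, 12 and 15 glia-like, in the sense of astrocytes, ependymal cells and tanycytes, from regulons such as Sox9, Nfia, Hes5 and Otx2. The 10 other clusters stayed unnamed and held 50.6% of the cells at E15, 46.1% at E17, 49.3% at P0, 56.5% and 47.4% at P2, 65% and 55.6% at P10, and 67.9% at P23. The neuron-like share was 41.4% of 7563 cells at E15 (exact Clopper-Pearson 95% interval 40.3% to 42.5%), 43.3% at E17, 31.3% at P0, 35.1% and 30.1% at P2, 27% and 28% at P10, and 24% of 421 cells at P23 (20% to 28.4%). It fell with age step over the 8 libraries (Spearman's rho = -0.928, exact two-sided permutation p = 0.00179, adjusted p = 0.00357 over 2 classes; Pearson's r = -0.919, exact permutation p = 0.00169, adjusted p = 0.00337). Without the 2 libraries farthest from the median age, where the second place was tied, r was -0.8 without E15 and E17 (exact permutation p = 0.0667) and -0.866 without E15 and P23 (exact permutation p = 0.0278), with adjusted p values of 0.133 and 0.0556. By either choice rho was -0.883. Only 6 libraries were left, and fewer samples alone can end a call, so how far the relation rested on these libraries was not settled. In batch 2 alone rho was -0.886 (exact permutation p = 0.0333, adjusted p = 0.0667) and r was -0.913 (exact permutation p = 0.0194, adjusted p = 0.0389). The clusters were defined in part by regulons that themselves changed with age, and at a clustering resolution of 2 rho was -0.675 (exact permutation p = 0.0754, adjusted p = 0.151). The share also depends on which clusters the rule named. Unnamed clusters 8, 9 and 13 each had 2 neuron markers among their top 10 regulons. Cluster 8 held 123 of 7563 cells at E15, 300 of 2364 and 293 of 1960 at P10, and 47 of 421 at P23. Cluster 13 held 43, 76 and 42, and 22 cells at these ages, and cluster 9 held 351, 59 and 43, and 9. Part of the fall may thus reflect the naming rule. The glia-like share had no trend that could be detected (rho = 0, exact permutation p = 1; r = 0.0195, exact permutation p = 0.962). It differed between libraries of 1 age, at 8.34% and 22.5% for P2 and 8.04% and 16.4% for P10. The intervals cover counting error only.

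**Figure D3:**
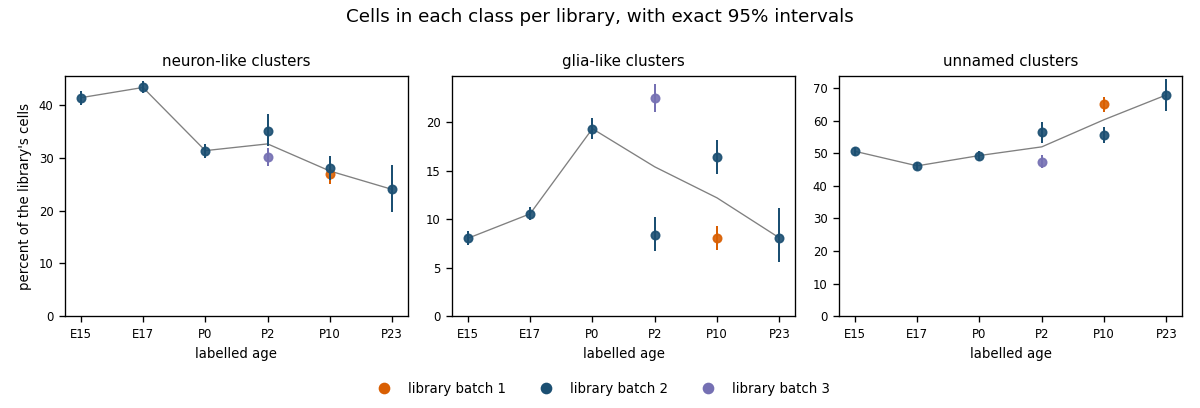
Percent of each library's cells (vertical axis) in neuron-like, glia-like and unnamed clusters against labelled age (horizontal axis). Points are libraries, coloured by library batch, bars are exact 95% binomial intervals, and grey lines join the means of the ages. The neuron-like share goes from 41.4% at E15 to 24% at P23.

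In the means over neuron-like cells, 28 regulons rose and 84 fell with age in limma at an adjusted p below 0.05. Of the regulons called over all cells, 21 of the 25 rises and 69 of the 70 falls were also called in this subset of the same cells. Hdac2, Sox4 and Sox11 again had the largest standardized decreases, and Sox4 went from 0.105 ± 0.0243 (SD, n = 2) in the embryonic to 0.04 ± 0.00177 (SD, n = 3) in the later postnatal libraries. The makeup of the class differed between these libraries: cluster 6, which Sox4, Sox11, Ezh2 and Kdm5b helped to define, held 26% and 23.9% of neuron-like cells at E15 and E17, 9.42% and 10.8% at P10, and 13.9% at P23. Rest, a repressor of neuronal genes in cells that are not neurons, fell from 0.0652 ± 0.00555 to 0.0173 ± 0.00181, and Ezh2, Smarca4, Sox12, Tcf12, Yy1, Kdm5b, Cux1 and Maz fell as well. Tef (0.0453 ± 0.00197 to 0.0745 ± 0.0114) and Pura (0.0371 ± 0.0187 to 0.268 ± 0.031) rose. So did Nfe2l1, Zeb1, Foxo1, Klf16, Tfe3, Hsf4, Nr3c2, the clock-linked repressor Bhlhe41 and Egr4, a factor induced by neuronal activity. The neuron list as a whole fell in these cells (fry adjusted p = 0.0436), with 9 of its regulons falling and 11 adjusted over the list alone, as did the immature neuron list (0.00485) and the cell cycle list (0.0143), and the activity, circadian and hormone list rose (0.0152). Camera was run only over all cells, where these lists did not pass with an estimated correlation (adjusted p = 0.809, 0.809, 0.809 and 0.667). With each cell centred, 69 regulons rose and 55 fell, against 25% rises among the calls as deposited and 55.6% when centred. There were 68 rises by rank, 7 by the share of cells above the 90th percentile, and 44 with library batch as a term and in batch 2 alone. Of the 24 regulons chosen by the naming rule, 16 lost their call by that share of cells, among them Sox11 (adjusted p = 0.0534), Ezh2 (0.0618), Pura (0.0843) and Tef (0.088), 13 without E15 and 9 without P23. Cux1 lost its call with library batch as a term and in batch 2 alone (adjusted p = 0.0548 and 0.0573), and Kdm5b in batch 2 alone (adjusted p = 0.0513). The counts were 8 and 34 without E15, and the rises numbered 15 without E17, 18 without P0, 15 without P23 and 47 without P10 replicate 1. The smallest library, P23, contributed 101 neuron-like cells.

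The last comparison tested whether the age slope differed between neuron-like and glia-like cells of the same libraries. Limma called 13 regulons, of which 12 had a lower slope in neuron-like cells. Pax6 went from 0.176 ± 0.0247 to 0.0725 ± 0.007 in neuron-like cells between the embryonic (n = 2) and later postnatal (n = 3) libraries, and from 0.159 ± 0.00419 to 0.129 ± 0.0143 in glia-like cells, a difference in slope of -0.0199 per age step (SE 0.00251, adjusted p = 0.0198). Glis1 went from 0.0216 ± 0.00673 to 0.0184 ± 0.00651 in neuron-like cells and from 0.0167 ± 0.00279 to 0.08 ± 0.00978 in glia-like cells. The neuronal factors Sox4, Sox11, Lhx1, Dlx5, Bcl11a and Pou3f1, and the chromatin and transcription factors Kdm5b, Nfyb and Mef2d were among the others with a lower slope in neuron-like cells. Tead3, which had a lower slope in glia-like cells, went from 0.0435 ± 0.0101 to 0.00333 ± 0.00313 there. In neuron-like cells it also fell, from 0.0165 ± 0.00639 to 0.00169 ± 0.00259, and on the log2 scale its difference in slope had an unadjusted limma p of 0.156. Sox4, Sox11, Bcl11a and Pou3f1 did not reach an unadjusted limma p of 0.05 on that scale either (0.0787, 0.0745, 0.23 and 0.582), while 8 of the 13 did. Glis1, Nfyb, Kdm5b, Pou3f1 and Tead3 are in none of the fixed lists and were named here after their values were seen. Different clusters made up the glia-like cells early and late: cluster 5 held 84% of them at E15, and cluster 15 held 73.5% at P23 and 90% in P10 replicate 2. The makeup of the neuron-like cells differed between libraries too, as given above. No call held with library batch as a term, at a clustering resolution of 2, where P23 held 12 glia-like cells and was left out, or without E17, P10 replicate 1 or P23 (0 calls in limma; 85, 94, 77, 94 and 91 regulons at an unadjusted p under 0.05), and without E15 the 1 call was of another regulon. With a mean-variance trend in the fit 3 slopes were called higher and 14 lower, all 13 calls among them. The counts of higher and lower slopes were 1 and 3 without P0, 5 and 19 without P2 replicate 1, 1 and 2 without P2 replicate 2, and 1 and 3 without P10 replicate 2.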

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

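Among the tests of explanations in this part, the bounds for the P10 libraries under centring and for slopes on the log2 scale were written before their results were seen. The tests of the excess of falls, of library batch, of the starting level and makeup of glia-like cells, and of other orders of the libraries were chosen or bounded after.

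A difference in age slope between neuron-like and glia-like cells brought 13 regulons up for a closer look. Among them, the slope in neuron-like cells minus that in glia-like cells, per age step, was -0.01988 for Pax6, -0.01546 for Glis1, -0.01008 for Bcl11a, -0.009831 for Lhx1, -0.008051 for Dlx5, -0.005627 for Nfyb, -0.005174 for Sox4, -0.004731 for Mef2d, -0.004651 for Sox11, -0.004215 for Kdm5b, -0.003211 for Pou3f1 and 0.006434 for Tead3. A low score in glia-like cells that leaves no room to fall might account for part of this, and the test did not decide: on the log2 scale 8 of the 13 kept the sign with an unadjusted p under 0.05, between the bounds of 6 and 10. Adjusted over all regulons, the lowest limma p of the 13 on that scale was 0.0522, so no call of the 13 passed there. A start in glia-like cells already at or below the level neuron-like cells ended at was not decided either: the embryonic glia-like mean lay above the later postnatal neuron-like mean for 10 of the 12 regulons with a lower neuron-like slope, but for 5 by more than both SDs, and these bounds were changed after the values had been seen. A change in the makeup of glia-like cells with age cannot be told apart from a change within them, since cluster 5 held as little as 5.9% of the glia-like cells of a library late and over 80% at the embryonic ages. The makeup of neuron-like cells differed as well. Cluster 6, which Sox4, Sox11 and Kdm5b helped to define, held 26% of them at E15, 9.42% and 10.8% at P10, and 13.9% at P23. The part of this in the 13 differences was not tested. A biological difference in timing between neurons and glia stays open and untested.

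More regulons fell than rose with age over all cells, 70 against 25. A shift of all scores together is a candidate explanation for this excess. With each cell centred, 46.4% of the calls were falls, but centring itself sets the mean slope over regulons to 0, so this value cannot decide. Fewer glia-like cells in later libraries would not give the excess, as 77.8% of the calls were falls outside glia-like clusters. Whether there was such a shift stays open, and depth is unknown. Of the calls as deposited, 25 rises and 50 falls were also called after centring.

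The P10 libraries differed from each other more than the P2 libraries did. The median absolute difference over regulons, in SDs between cells, was 0.528 for P10 and 0.282 for P2, and 5 of the 28 pairs of libraries were farther apart than the P10 pair. A shift of all scores by the same amount did not account for all of it. With each cell centred the P10 value was 0.4446 (95% bootstrap interval over regulons 0.391 to 0.493) and the P2 value 0.307 (0.279 to 0.356). Centring takes out 1 amount per cell, so a shift in proportion to the scores cannot be excluded by it. The intervals resample the regulons of 1 pair of libraries per age, and do not measure the spread between pairs. Library batch and library cannot be told apart, because batch 1 holds 1 library. A difference between animals or dissections stays open.

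Other orders of the libraries were set against the counts of calls. Of 100 orders of the ages, the real one included, 1 gave as many calls as the 95 over all cells (highest other 41) and 1 as many as the 112 in neuron-like cells (highest other 86). The real order thus gave the most calls of the 100 orders drawn. This makes a chance order of the ages unlikely for both, but 100 orders do not exclude it. For the change from neonatal to later postnatal libraries, 1 of the 10 splits of the 6 libraries gave as many as the 21 calls (highest other 0), and 10 splits are too few for a share under 0.05.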

How the results depend on the processing

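Over the alternatives run, none of the 69 results on named regulons changed direction: of 1382 values, 1124 kept their side of the threshold, 251 no longer passed and 7 newly passed. The runs outside glia-like clusters, in batch 2 alone for regulons and lists, with lists in neuron-like cells, with a mean-variance trend for the difference in slopes and without the 2 farthest libraries were chosen after the data had been seen. The cause of the changes below was not tested, except that leaving out libraries or taking batch 2 alone means fewer samples. The replicate block is library batch, which takes up the lone libraries of batches 1 and 3. Depth is unknown and its effect was not tested. Where E15 or E17 is left out, the lone embryonic library is assumed to vary like the others.

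Over all cells (25 rises, 70 falls), rises numbered 60 when centred, 62 by rank, 5 by the share of cells above the 90th percentile, 43 with library batch as replicate block and 40 in batch 2 alone; leaving out each library gave 6 to 43 rises and 30 to 70 falls. From embryonic to neonatal (1 and 1), limma gave 0 and 0 when centred, by the share of cells, without trend, with the replicate block and in batch 2 alone (46, 54, 34, 33 and 32 at an unadjusted p under 0.05), 5 and 6 by rank, 3 and 0 on the log2 scale and 2 and 4 outside glia-like clusters; leaving out each library gave 0 to 3 and 0 to 8. From neonatal to later postnatal (3 and 18), falls numbered 4 when centred, 0 by the share of cells (66 regulons at an unadjusted p under 0.05 in limma), 43 on the log2 scale, 10 without trend, 29 outside glia-like clusters and 2 with the replicate block or in batch 2 alone, and rises 20 by rank; leaving out each library gave 2 to 10 rises and 2 to 23 falls. In neuron-like cells (28 and 84), there were 69 rises and 55 falls when centred, and 68 rises by rank, 7 by the share of cells and 44 with the replicate block or in batch 2 alone; leaving out each library gave 8 to 47 and 34 to 87. For slopes that differed between neuron-like and glia-like cells (1 higher, 12 lower), eBayes with trend gave 3 and 14, a resolution of 2 and the replicate block gave 0 and 0 in limma (94 and 85 at an unadjusted p under 0.05), the first also without P23, which then held 12 glia-like cells, and leaving out each library 0 to 5 and 0 to 19.

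Among the lists, the neuron list passed with the preset correlation (adjusted p = 0.0262), when centred (0.0439) and in neuron-like cells (0.0436). With an estimated correlation the neuron, immature neuron and cell cycle lists had an adjusted p of 0.809 and the activity list 0.667. Leaving out each library gave 0.0177 to 0.145 for the cell cycle list, 0.017 to 0.116 for the activity list, 0.0391 to 0.228 for the microglial list and 0.299 to 0.929 for the lymphocyte list. The lymphocyte list, not past the threshold, turned upward when centred (0.946), with the replicate block (0.787), in batch 2 alone (0.862) and without P10 replicate 1 (0.929), and the broad transcription list when centred (0.975). The replicate block changed no call of a list. For the glia-like share, rho ranged from -0.509 to 0.2 without each library and never passed. For the neuron-like share, rho was -0.675 at a resolution of 2, -0.886 in batch 2 alone and -0.883 without the 2 farthest libraries, by either choice, and did not pass by rho in these; a resolution of 0.5 and each library left out kept the call.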

Other observations

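Some clusters that stayed unnamed were led by regulons of known neuron groups; their regulons were named here after the values were seen. Cluster 9, with 1605 cells, was led by Lhx9, Gbx2, Shox2, Lhx2 and Tcf7l2, of which Gbx2, Lhx9 and Tcf7l2 are known from thalamic neurons. Cluster 13, with 533 cells, was led by Pou3f2, Fosl2, Foxb2 and Otp; Otp and Pou3f2 are known from neuroendocrine neurons. Cluster 14, with 532 cells, was led by Rorb, Creb3l1, Hlf and Nr1d1, several of them clock-linked, and cluster 16, with 233 cells, by Foxo4, Foxo1 and the steroid receptors Nr3c1 and Nr3c2. At a resolution of 2 a cluster of 190 cells was led by Rax, Bcl6, Creb5 and Foxj1; Rax is known from tanycytes. It held 61 and 107 cells of the P10 libraries, 21 of P23 and 1 of P0. These regulons define the clusters, so their levels there are not results, and a cluster filled by a few libraries can reflect those libraries.

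Several regulons were highest in the 3 neonatal libraries. In 8 regulons, among them Ctcf, Cic, Nfe2, Carf, Trp53, Runx1 and Hes5, every neonatal library lay above all 5 others, where chance gives 1.79% of regulons, or 7.05 of 395. These were named after their values were seen. The hypothesis of a neonatal peak beyond a steady trend was tested against the other sets of 3 libraries, with its bound written beforehand. Of 56 sets, 15 had as many such regulons, the neonatal set included, and the highest other had 41. That was a late set, P2 replicate 1, P10 replicate 2 and P23, followed by an early set, E15, E17 and P2 replicate 1 (36). A steady trend alone raises such sets and makes middle ages less often highest. The chance value treats all sets of 3 alike. The count therefore cannot decide whether there was a neonatal peak beyond a trend. Centred, there were 6 such regulons, of which 4 were shared.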
